A study of Homo sapiens with 36 samples.

How the data were processed

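The series measured RNA by targeted RNA-Seq in 36 human lymphoma cell lines, with 1 library per line. Per the labels, cells were lysed in buffer, treated with proteinase K and plated at 10000 cells per well, samples were run as singletons, and the barcoded libraries were sequenced on an Illumina NextSeq. Genome build hg38 is named in the submitters' processing notes. The aligner, the counting method, and whether counting used strand are not given in the sources used here.

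The deposited count table gave the count of each of 2559 targets in each of the 36 libraries as whole numbers with no scaling. Of these, 10 were named ER and a number. Their identity is not stated, and they were treated as control probes that name no gene, since they drew few counts in most libraries. They held a median of 0.000209% of the counts (at most 0.0265%, in MEC1) and were left out of library sizes and tests. The second deposited table held log2 values, which the authors had made from the counts: each equalled the log2 of the count divided by 1 factor per library, plus 1, within 0.00588. The authors' factors differed from median-of-ratios factors by a median of 0.00594 log2 units. These log2 values served as an alternative to the scaling used here. All 36 sample columns were used.

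Counts were scaled in edgeR 4.0.16 by TMM factors and converted to CPM, and to log2 CPM with a prior count of 2. Genes were kept for tests with at least 10 CPM in at least 4 lines, which left 2406 of 2549. Genes above background were those above the highest such probe of the library. Library totals ran from 6422940 to 13451686 counts. Intervals are exact Poisson intervals of the count at 95%, and a count of 0 is taken to allow 3 counts. As molecules were not individually tagged in the tables, both cover counting error only. Symbols were used as the table gives them. Of the 2549 names, 2492 equalled a current symbol and 2501 had 1 record in GENCODE release 29, from which coordinates on GRCh38 were taken. Genes with near-identical copies or overlapping transcripts could share reads, so their levels are less certain. Genes whose level would show a donor's sex were left out of the gene values given.

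The spread of each gene was its SD of log2 CPM across lines, with a 95% interval from resampling lines and the share of the variance that Poisson counting error would give. In total 23 lists holding 328 genes were fixed, of which 238 genes were in the panel. A list was called coherent where the median Spearman rho between its members lay above an upper limit. That limit was the upper end of the central 95% of 10000 random lists of the same size and like mean expression. Such a call describes these libraries and gives no p. A further 60 pairs of genes or list scores were fixed. A score was the mean z-score of a list's members, leaving out genes on both sides. Of the pairs, 10 had a side that was not measured. Where a gene had a gap of at least 1.5 log2 units and 20% of its range with at least 4 lines on each side, correlations were computed within each cluster of at least 6 lines, which gave 56 relations. Each had a Pearson r and a Spearman rho with two-sided permutation tests of 100000 resamples (exact where fewer than 10 lines), Benjamini-Hochberg adjusted over the 56, and passed where both adjusted p were under 0.05. Each r was computed again without the 2 lines farthest from the median of the first measure.

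Slopes were fitted for BCL6, MYC and MKI67 by the edgeR quasi-likelihood test of each other gene on the log2 CPM of the named gene across 36 lines, with Benjamini-Hochberg adjustment over 2405 genes. The SE given is the slope divided by the square root of its F statistic. IRF4 and CCND1 were to be fitted in the same way and were not, because their lines fell into separate clusters. Lists with at least 4 measured members were tested by camera in limma 3.58.1 with a correlation of 0.01, adjusted over lists, and again with an estimated correlation. Members were counted over all genes and adjusted over the list alone. The values of each named gene were also permuted over lines 100 times.

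Genes were named by a rule: the 25 with the largest SD, for each fit the 10 largest positive and 10 largest negative slopes past the threshold that kept their sign without the 2 lines with the most extreme values, members of the lists, and both sides of each pair. Results for some genes, with 1 list and the pairs that need them, are not reported here. The lists, pairs, tests, rule and first set of alternatives were fixed before the data were examined. Those alternatives were DESeq2 1.42.0 size factors, upper-quartile factors, library size alone, prior counts of 0.5 and 10, no filter, a filter at 50 CPM, the authors' log2 values, log2 library size as a covariate or regressed out, 10 counts or 50 CPM as background, the DESeq2 Wald test, limma-voom, the rank of the named gene, and fits without the 2 farthest lines. Chosen after seeing the data were the log2 TMM factor as a covariate or regressed out, results without MEC1, each line left out in turn from the slopes, and the scalings tried on the lines low in IRF4 or high in CCND1.

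The steps were tested on simulated data with 200 of 2405 genes changed. Slopes of 1 were recovered for 97% of genes with BCL6, 97% with MYC and 92.4% with MKI67, slopes of 0.5 for 77.6%, 61.2% and 62.7%, and slopes of 0.25 for 19.4%, 11.9% and 11.9%. False calls were 7.19%, 6.61% and 2.63% of calls. The simulated genes were independent and their libraries did not differ in composition, so these shares do not cover calls that follow the TMM factor. Of the simulated lists, 10 of 10 with a shared factor and 0 of 10 without were called, and of the simulated pairs 50 of 50 with a correlation of 0.7 and 0 of 50 with none. R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.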

Results

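Expression of a fixed panel of 2549 genes was counted by targeted RNA-Seq in lysates of 36 human lymphoma cell lines. Each line gave 1 library, and no line was measured more than once. The lines are immortalised B-cell cultures used as laboratory models of lymphoma. The labels name the lines and place them in no groups, so every comparison is of levels across the 36 lines, and no value has an error between replicates. Total counts per library ran from 6422940 in HAIR_M to 13451686 in SUDHL6, with a median of 10476691. A median of 2436 genes per library lay above that library's highest control probe, from 2318 in TOLEDO to 2500 in DOHH2. Levels are given as CPM, counts scaled by library size and the TMM factor. A count of 0 allowed up to 0.474 CPM in the library with the highest such limit, OCILY8. That limit, like the intervals given, covers counting error only. The MEC1 library stood apart. Its highest control probe had 424 counts against a median of 10 and a next highest value of 64, and its lowest gene had 174 counts.

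IRF4, a transcription factor needed for plasma cell formation, was close to absent in 7 lines and abundant in the others. It was under 10 CPM in KARPAS422 (1.10 CPM), SUDHL10 (3.15), WSU_DLCL2 (3.19), DB (3.61), SUDHL4 (4.65), SUDHL16 (5.89) and OCILY1 (8.31). The highest levels were in DOHH2 (1746 CPM), MAVER1 (1630 CPM) and JVM2 (1425 CPM), and the median line had 471 CPM. A gap of 3.24 log2 units, 31.1% of the range, separated the 7 low lines from the other 29. The gene lies on chromosome 6 at 391739 to 411447 of hg38.

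CCND1, the D-type cyclin placed under the immunoglobulin heavy-chain enhancer by the translocation of mantle cell lymphoma, stood far above the rest in 4 lines. MAVER1 had 24020 CPM, MINO 13370, GRANTA519 2771 and JVM2 2051, and all 4 are known to carry that translocation. The next lines were VL51 at 270 CPM and FARAGE at 268 CPM, below a gap of 2.92 log2 units. Of the other lines known to carry it, REC1 had 91.2 CPM (95% interval 86.2 to 96.4), SP49 27.4, UPN1 13.0, JEKO1 8.77 and SP53 7.90. CCND2, another D-type cyclin, was highest in JVM2 (3474 CPM), VL51 (3388), HBL1 (1938), HC_1 (1666) and HAIR_M (1300). CCND3, the remaining D-type cyclin, was highest in SUDHL6 (2252 CPM) and OCILY19 (1712 CPM). Because IRF4 and CCND1 each fell into 2 clusters of lines, no slope on either gene was fitted over all lines.

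**Figure D1:**
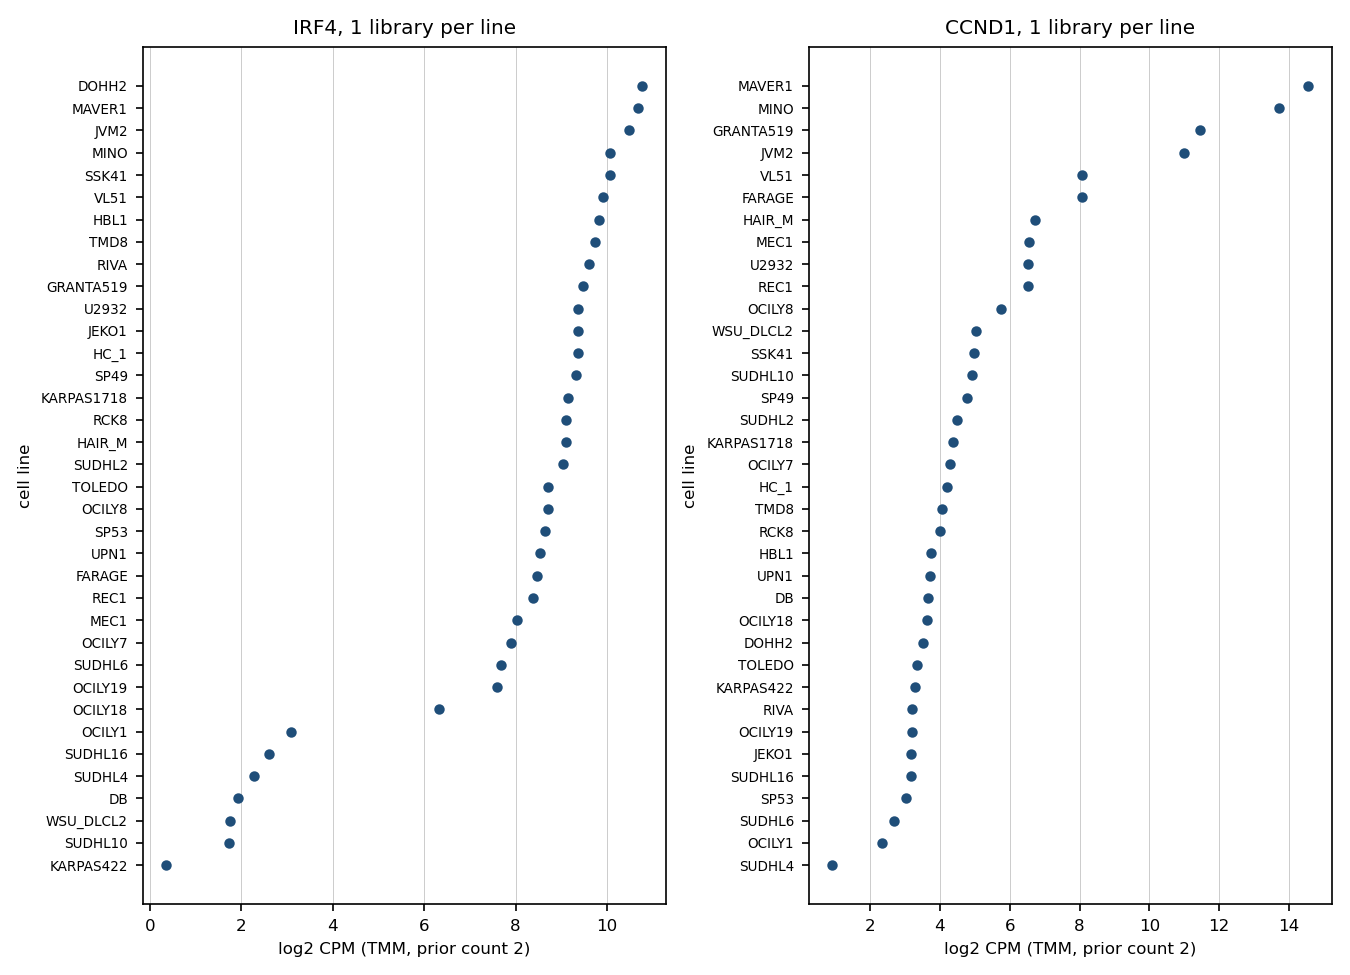
Level of IRF4 and of CCND1 in each of the 36 lines, in log2 CPM, with 1 point per library. IRF4 leaves a gap of 3.24 log2 units above its 7 lowest lines, and CCND1 a gap of 2.92 log2 units below its 4 highest.

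Single genes stood far from their median level in some lines. CDKN2A, which encodes the cell cycle inhibitor p16, was under 10 CPM in 9 lines, lowest in MAVER1 (0.29 CPM), SP49 (0.39) and DOHH2 (0.61), and highest in KARPAS1718 (477 CPM). DNTT, the template-free DNA polymerase of immature lymphocytes, reached 6971 CPM in OCILY19 and 931 CPM in TOLEDO against a median of 1.78 CPM. HLA-B, which presents peptides to T cells, was at 51.7 CPM in DB and 283 CPM in REC1 against a median of 4790 CPM.

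The genes that differed most between lines included surface receptors, chemokines and lineage regulators. SLAMF7, a receptor of plasma cells and natural killer cells, had the largest SD (3.44 log2 units, 2.89 to 3.89 by resampling lines) and reached 2362 CPM in FARAGE. CDH2, which encodes N-cadherin, was under 10 CPM in 29 lines and reached 2798 CPM in U2932. CCL22, a chemokine that attracts regulatory T cells, ran from 5.21 CPM in SUDHL4 to 16380 CPM in HAIR_M, and CCL4, another chemokine, reached 4852 CPM in JVM2. TCL1A, an AKT coactivator of naive and germinal centre B cells, ran from 10.4 CPM in VL51 to 8831 CPM in JEKO1. FCER2, the low-affinity IgE receptor CD23, was highest in VL51 (3855 CPM) and GRANTA519 (2629 CPM). MX1, an interferon-induced antiviral GTPase, ran from 1.81 CPM in SUDHL4 to 5708 CPM in MAVER1. ANXA1, a phospholipid-binding protein, was under 10 CPM in 28 lines and reached 6068 CPM in SUDHL16, and IGFBP2, which binds insulin-like growth factors, reached 9714 CPM in DOHH2. Also among the 25 genes with the largest SD were PLA1A, EFNA5, INPP5J, CXCR3, CACNA2D1, CACNA2D3, TSPAN13, ENG, ZBTB32, GNAQ and PRKCZ, with CCND1, DNTT, IRF4 and CDKN2A. Across 2406 genes that passed the filter the median SD was 1.20 log2 units. In all, 211 genes (8.77%) had an SD above 2, and counting error made up at most 9.37% of the variance of any of them.

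Members of 8 of the 22 gene lists tested rose and fell together across lines. Cell cycle genes had a median Spearman rho of 0.583 between members, and interferon response genes, such as MX1 and STAT2, 0.466. MHC class I and antigen processing genes, such as HLA-B and TAP2, had 0.634, and NF-kB target genes, such as CCL22 and NFKB1, 0.320. Immune checkpoint and costimulation genes, such as PDCD1LG2 and CD40, had 0.275, MYC target genes, such as TERT and PPAT, 0.264, and germinal centre B-cell genes, such as NEIL1 and EZH2, 0.259. These 7 lists lay above the upper limit of random lists of like expression both as measured and after the values were regressed on the log2 TMM factor, a measure of library composition. The eighth, epithelial markers such as CDH1 and KRT8, had 0.368 as measured and 0.136 after that regression, at the 95.28th percentile of its random lists and below the limit.

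The other 14 lists tested did not pass as measured. Among those that did after the regression were activated B-cell genes (median rho 0.177, then 0.194), JAK-STAT target genes (0.085, then 0.092) and T and NK cell markers (0.573, then 0.382). Those that passed neither way were plasma cell genes (0.089), B-cell lineage genes (0.059), B-cell receptor and PI3K signalling genes (0.109), BCL2 family genes (0.089), G1 cyclin and inhibitor genes (0.041), homing receptor genes (0.068), NOTCH pathway genes (0.009), cancer-testis genes (0.593), myeloid markers (0.408) and stromal and endothelial markers (0.333). The MHC class II list had 1 measured member, CD74, the invariant chain, at a median of 14.48 log2 CPM, and was not tested.

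**Figure D2:**
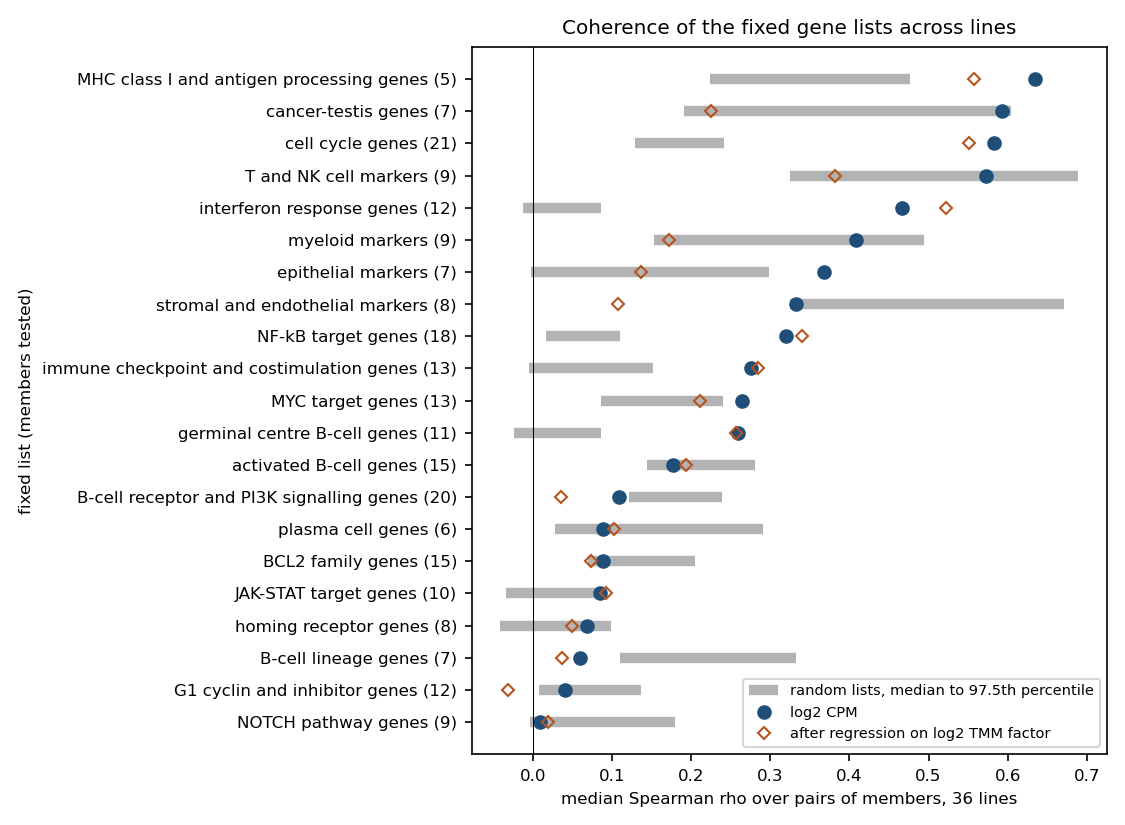
Median Spearman rho over pairs of members of lists across the 36 lines, as measured (filled points) and after regression on the log2 TMM factor (open diamonds), with grey bars from the median to the upper limit of 10000 random lists. Cell cycle, MHC class I and interferon response genes lie farthest above the median of their random lists.

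Levels of germinal centre and activated B-cell genes ran in opposite directions across lines. The scores of the germinal centre and activated B-cell lists had r = -0.50 (permutation p = 0.0019, adjusted p = 0.007) and rho = -0.55 (permutation p = 0.00072, adjusted p = 0.005), and r = -0.53 without SUDHL4 and WSU_DLCL2. BCL6, the repressor that maintains the germinal centre state, went with MME, the surface enzyme CD10 (r = 0.47, permutation p = 0.0038, adjusted p = 0.013; rho = 0.51, permutation p = 0.0016, adjusted p = 0.007; r = 0.39 without SUDHL16 and OCILY1). It also went with MYBL1, a transcription factor of germinal centre cells (r = 0.50, permutation p = 0.0016, adjusted p = 0.0064; rho = 0.47, permutation p = 0.0045, adjusted p = 0.016; r = 0.46 without the same lines). Among the 29 lines above the IRF4 gap, IRF4 and MME were opposed (r = -0.50, permutation p = 0.0055, adjusted p = 0.016; rho = -0.50, permutation p = 0.0069, adjusted p = 0.023; r = -0.53 without OCILY18 and DOHH2). Among the 7 lines below the gap the relation had the other sign and did not pass (r = 0.61, exact p = 0.15, adjusted p = 0.24; rho = 0.54, exact p = 0.24, adjusted p = 0.34; r = -0.19 without KARPAS422 and OCILY1). BCL6 and PRDM1, the plasma cell regulator, had r = -0.34 (permutation p = 0.043, adjusted p = 0.097) and rho = -0.41 (permutation p = 0.014, adjusted p = 0.040), and did not pass both tests. That pair passed without JEKO1 or without SUDHL16. BCL6 showed no such relation with LMO2 (r = -0.14, permutation p = 0.42, adjusted p = 0.49; rho = 0.12, permutation p = 0.49, adjusted p = 0.56).

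NF-kB targets and immune genes gave several of the pairs that passed. NFKBIA and TNFAIP3, feedback inhibitors of NF-kB that are themselves its targets, had r = 0.78 (adjusted p = 9.3e-05) and rho = 0.82 (adjusted p = 0.00014), each at a permutation p of 1e-05, the smallest that 100000 permutations can give, and r = 0.81 without SUDHL2 and RCK8. The NF-kB and activated B-cell list scores had r = 0.66 (adjusted p = 9.3e-05) and rho = 0.68 (adjusted p = 0.00014), each at a permutation p of 1e-05, and r = 0.63 without KARPAS422 and JVM2. CD274 and PDCD1LG2, which encode the PD-1 ligands PD-L1 and PD-L2, had r = 0.71 (adjusted p = 9.3e-05) and rho = 0.69 (adjusted p = 0.00014), each at a permutation p of 1e-05, and r = 0.75 without JEKO1 and RCK8. CD274 was highest in RCK8 (1073 CPM) and VL51 (811 CPM). It also went with STAT3, a cytokine-activated transcription factor (r = 0.55, permutation p = 0.00049, adjusted p = 0.0027; rho = 0.51, permutation p = 0.0018, adjusted p = 0.0071; r = 0.45 without the same lines). STAT3 went with SOCS3, its feedback inhibitor (r = 0.55, permutation p = 0.0004, adjusted p = 0.0025; rho = 0.50, permutation p = 0.0024, adjusted p = 0.0091; r = 0.48 without SUDHL2 and TMD8). Interferon response and MHC class I list scores had r = 0.68 (permutation p = 1e-05, adjusted p = 9.3e-05) and rho = 0.68 (permutation p = 2e-05, adjusted p = 0.00022), and r = 0.64 without SUDHL16 and MAVER1. MAVER1 scored high on both lists (1.85 and 1.58 mean z-score), and DB low on both (-0.87 and -1.28).

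**Figure D3:**
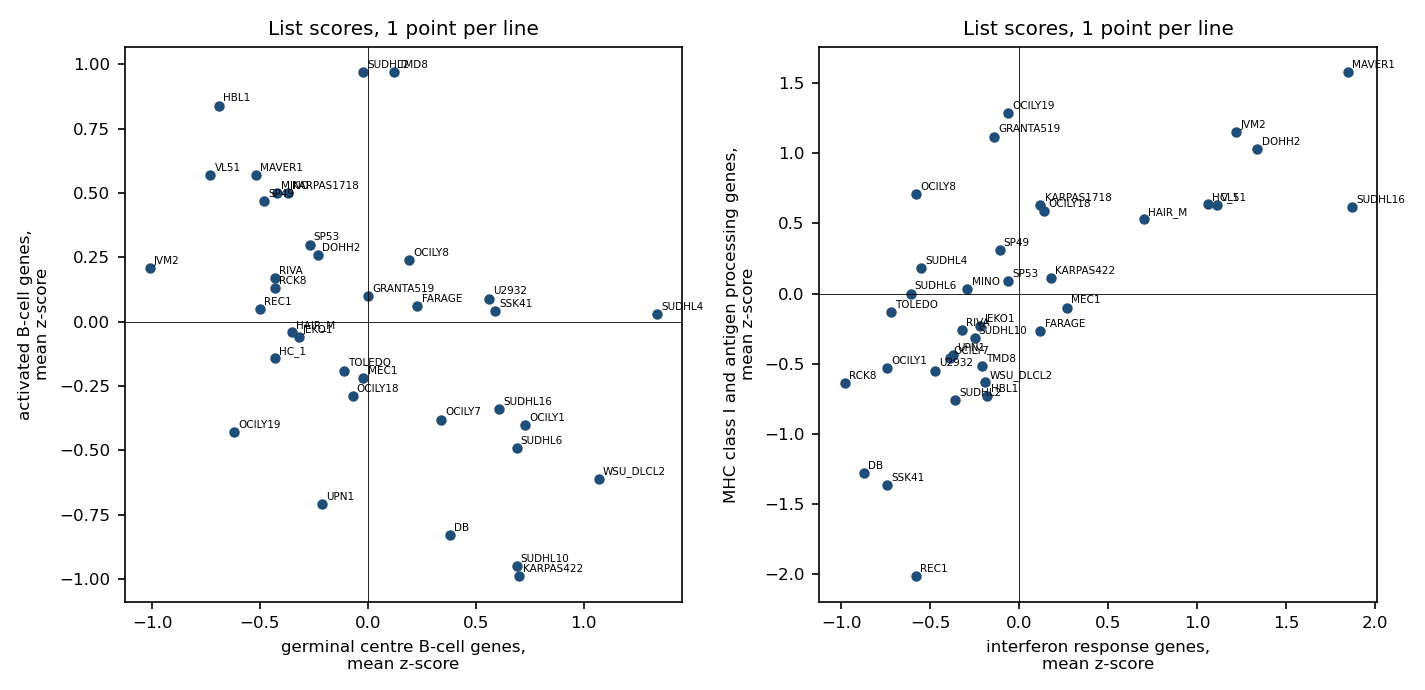
Scores of the germinal centre list against the activated B-cell list, and of the interferon response list against the MHC class I list, as mean z-scores with 1 point per line. The first pair runs downward (r = -0.50) and the second upward (r = 0.68).

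Proliferation genes and the CDKN2 locus gave further pairs. MKI67, which encodes the proliferation marker Ki-67, and TOP2A, a topoisomerase of dividing cells, had r = 0.83 (adjusted p = 9.3e-05) and rho = 0.81 (adjusted p = 0.00014), each at a permutation p of 1e-05, and r = 0.78 without SUDHL2 and GRANTA519. Cell cycle and MYC target list scores had r = 0.70 (permutation p = 1e-05, adjusted p = 9.3e-05) and rho = 0.62 (permutation p = 9e-05, adjusted p = 0.00084), and r = 0.66 without SUDHL2 and WSU_DLCL2. CDKN2A and CDKN2B, neighbours on chromosome 9 that both encode cell cycle inhibitors, had r = 0.70 (permutation p = 2e-05, adjusted p = 0.00016) and rho = 0.51 (permutation p = 0.0015, adjusted p = 0.007), and r = 0.64 without MAVER1 and SP49. CDKN2B was low, with a median of 11.1 CPM, under 10 CPM in 17 lines and at most 74.7 CPM, in OCILY7. The kinase genes BTK and SYK, which act below the B-cell receptor, had r = 0.55 (permutation p = 0.00023, adjusted p = 0.0016) and rho = 0.51 (permutation p = 0.0014, adjusted p = 0.007), and r = 0.49 without RCK8 and TOLEDO. MDM2, which encodes a ubiquitin ligase, and CDKN1A, which encodes the cell cycle inhibitor p21, had r = 0.45 (permutation p = 0.0064, adjusted p = 0.018) and rho = 0.44 (permutation p = 0.0082, adjusted p = 0.024), and r = 0.51 without MEC1 and OCILY8. That call was lost when OCILY19, RCK8 or VL51 was left out.

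Some pairs passed as measured and did not pass after regression on the log2 TMM factor. MKI67 with EZH2, a histone methyltransferase, had r = 0.53 (permutation p = 0.00094, adjusted p = 0.0044; rho = 0.59, permutation p = 0.00021, adjusted p = 0.0017; r = 0.61 without SUDHL2 and GRANTA519), and 0.36 after it. MYC with the MYC target list had r = 0.52 (permutation p = 0.0011, adjusted p = 0.0047; rho = 0.52, permutation p = 0.0015, adjusted p = 0.007; r = 0.57 without UPN1 and U2932), and 0.22 after it. MKI67 with the MYC target list had r = 0.52 (permutation p = 0.00086, adjusted p = 0.0044; rho = 0.52, permutation p = 0.0013, adjusted p = 0.007; r = 0.46 without SUDHL2 and GRANTA519), and 0.32 after it. MYC with NCL, which encodes nucleolin, had r = 0.47 (permutation p = 0.0038, adjusted p = 0.013; rho = 0.44, permutation p = 0.0077, adjusted p = 0.024; r = 0.50 without UPN1 and U2932), and 0.16 after it, and was also lost without OCILY8 or U2932.

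In total 20 of the 56 relations computed passed, 18 positive and 2 negative, and all adjusted p-values given cover those 56. The other 36 did not pass.

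Libraries also differed in composition. The first principal component held 28.4% of the variance and followed the log2 TMM factor (absolute r = 0.892, permutation p = 1e-05, adjusted p = 9e-05; absolute rho = 0.871, permutation p = 1e-05, adjusted p = 9e-05; 9 relations; absolute r = 0.864 without MEC1 and OCILY8). The factor ran from 0.602 in OCILY8 to 1.87 in MEC1. As it increased, 14 of 21 cell cycle genes, 12 of 20 B-cell receptor and PI3K signalling genes and 9 of 13 MYC target genes fell. At the same time 6 of 9 T and NK cell markers, 6 of 9 myeloid markers, 6 of 8 stromal and endothelial markers, 4 of 7 cancer-testis genes and 4 of 7 epithelial markers rose. Over all genes the direction went with the level: of the 602 genes lowest in mean level 400 rose, and of the 602 highest 461 fell. CPM are divided by this factor, so a gene with a steady share of its library falls with a slope of -1. Median slopes were -0.9 for cell cycle, -0.96 for B-cell receptor and PI3K signalling and -1 for MYC target genes. In the 602 highest genes the median was -1.09, so the falls of these lists are near what scaling alone gives. MYC went against the factor (r = -0.601, permutation p = 0.00013, adjusted p = 0.00039; rho = -0.656, permutation p = 2e-05, adjusted p = 6e-05; r = -0.534 without MEC1 and OCILY8), as did MKI67 (r = -0.473, permutation p = 0.0038, adjusted p = 0.0056; rho = -0.456, permutation p = 0.0057, adjusted p = 0.0086; r = -0.525). BCL6 showed no relation to it (r = 0.128, permutation p = 0.46, adjusted p = 0.46; rho = 0.242, permutation p = 0.15, adjusted p = 0.15; r = 0.126). These levels are themselves divided by the factor, which the permutation p-values do not allow for. The numbers of genes called below are therefore given with and without the factor in the fit.

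Lines with more BCL6 had more of some other germinal centre genes. BCL6 itself was low, with a median of 17.2 CPM, under 10 CPM in 11 lines and over 100 CPM in 2. Per log2 unit of BCL6, SERPINA9, a protease inhibitor of germinal centre B cells, rose by 1.27 ± 0.20 log2 units (SE, n = 36, adjusted p = 6.99e-05), and MAPK10, a JNK kinase, by 0.91 ± 0.16 (adjusted p = 0.000322). ITPKB, an inositol kinase, rose by 0.43 ± 0.11 (adjusted p = 0.0145) and ASB13 by 0.63 ± 0.17 (adjusted p = 0.0189). Thus 4 of 10 germinal centre members rose, none fell and 6 were not called, while 7 rose when adjusted over the list alone. The list's median slope was 0.47, with a camera adjusted p of 1.2e-05, and an adjusted p = 0.0249 with an estimated correlation.

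CCR7, the receptor that draws lymphocytes to lymph nodes, fell by 1.14 ± 0.21 log2 units per unit of BCL6 (adjusted p = 0.000409), and CCND1 by 1.65 ± 0.33 (adjusted p = 0.0012). FCER2 fell by 1.30 ± 0.31 (adjusted p = 0.0101) and CRY1, a circadian repressor, by 1.07 ± 0.26 (adjusted p = 0.0118). Among the signalling genes PIK3CD, a PI3K catalytic subunit, fell by 0.30 ± 0.07 (adjusted p = 0.00945) and the adaptor GAB1 by 0.47 ± 0.11 (adjusted p = 0.0082). In the same list PIK3CG, another catalytic subunit, rose by 0.51 ± 0.12 (adjusted p = 0.0101) and PLCG2, the phospholipase below BTK, by 0.31 ± 0.07 (adjusted p = 0.00357). Outside the lists PDGFD, a growth factor, rose by 0.72 ± 0.11 and COL4A3, a basement membrane collagen, by 0.73 ± 0.11, each at an adjusted p of 6.99e-05. TUBB3, NCAM1, DAPL1, ALDH1A1, THY1 and MET also rose, and DNTT, PLA1A, ENG, TNFRSF8 and CCND2 also fell, all within the 10 largest slopes in their direction. Several of these genes were less closely tied to BCL6 by other measures. Least-squares slopes on log2 CPM were -0.65 for CCND1, -0.59 for PLA1A, -0.50 for DNTT, -0.42 for CCND2, -0.31 for TNFRSF8, 0.44 for DAPL1, 0.35 for THY1 and 0.31 for MET, each under 0.5 of the slope in the edgeR fit. DAPL1, PLA1A, ENG, TNFRSF8 and CCND2 passed by neither r nor rho (adjusted p from 0.062 to 0.43), MET did not pass by r (adjusted p = 0.097) and ASB13 did not by rho (adjusted p = 0.051). CCND1 had r = -0.364 (permutation p = 0.028, adjusted p = 0.040; r = -0.311 without SUDHL16 and OCILY1) and rho = -0.246 (permutation p = 0.15, adjusted p = 0.17), among 35 relations. DNTT had r = -0.280 (permutation p = 0.099, adjusted p = 0.11; r = -0.366 without the same lines) and rho = -0.127 (permutation p = 0.46, adjusted p = 0.46). CCND1 falls into separate clusters of lines, so its pooled r and slope may rest on the 4 lines above its gap. Fits without those lines together were not run. It also remains possible that the probe misses the CCND1 transcript in JEKO1, UPN1, SP53, SP49 and REC1.

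**Figure D4:**
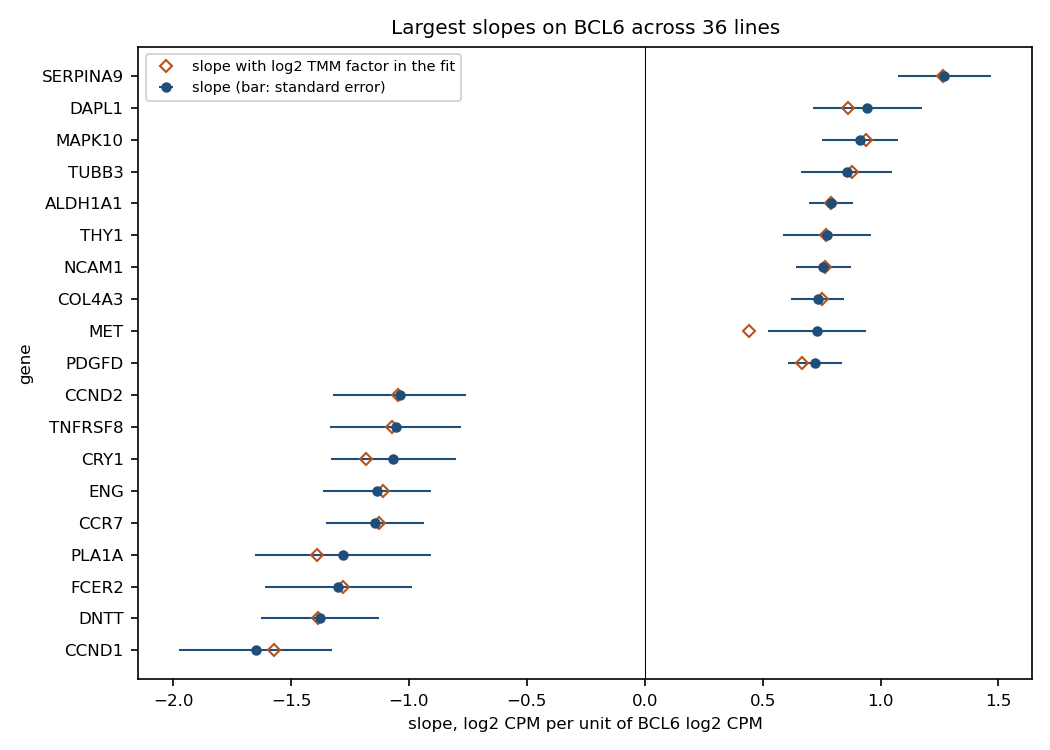
Slopes of genes among the 10 with the largest positive and the 10 with the largest negative slope on BCL6, in log2 CPM per log2 unit of BCL6 over the 36 lines, with bars for the standard error and open diamonds for the slope with the log2 TMM factor in the fit. SERPINA9 has the largest positive slope (1.27) and CCND1, which falls into separate clusters of lines, the largest negative one (-1.65). MET is the gene that shifts most, to 0.44.

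Across 2405 genes, 46 rose and 60 fell with BCL6 at an adjusted p under 0.05 in the edgeR quasi-likelihood test, and 97 of the 106 stayed with the log2 TMM factor in the fit, which called 165 (74 rose and 91 fell). Camera called 6 further lists, all lost with an estimated correlation. NF-kB target genes were lower (adjusted p = 0.0103; 3 of 18 fell, 4 when adjusted over the list alone; adjusted p = 0.543 with an estimated correlation). So were activated B-cell genes (adjusted p = 0.0103; 2 of 15 fell, 3 when adjusted over the list alone; adjusted p = 0.427 with an estimated correlation). Homing receptor genes had an adjusted p of 0.0103 (1 of 8 fell, and 3 fell and 1 rose when adjusted over the list alone; adjusted p = 0.154 with an estimated correlation). MHC class I genes were tested as lower with no member called (adjusted p = 0.0103; 3 of 5 fell when adjusted over the list alone; adjusted p = 0.414 with an estimated correlation), as were plasma cell genes (adjusted p = 0.0338; 0 of 6 when adjusted over the list alone; adjusted p = 0.173 with an estimated correlation). Epithelial markers were tested as higher with no member called (adjusted p = 0.0475; 6 of 7 rose when adjusted over the list alone; adjusted p = 0.469 with an estimated correlation). That camera call was also lost without MEC1 (adjusted p = 0.0802; 1 of 7 when adjusted over the list alone) and with the log2 TMM factor (adjusted p = 0.0765). B-cell lineage genes, which were not called, had a median slope of 0.05, a mean of -0.13 and a downward test. Scaling changed the balance most, with 522 genes rising and 50 falling under upper-quartile factors and 662 and 61 under library size alone. Leaving out SUDHL16 gave 210 genes and ended the ALDH1A1 and ASB13 calls, and leaving out OCILY19 ended those of DNTT and ENG, SUDHL4 those of DAPL1 and THY1, VL51 that of TNFRSF8 and JVM2 or VL51 that of CCND2. The PLA1A call was lost in 9 of the 36 leave-one-out runs and that of MET in 5, and the MET call was also lost with the log2 TMM factor (0.44, adjusted p = 0.0579).

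Lines with more MKI67 had more of nearly every cell cycle gene. Per log2 unit of MKI67, BUB1, a spindle checkpoint kinase, rose by 0.70 ± 0.09 log2 units and cyclin B1 (CCNB1) by 0.61 ± 0.08, each at an adjusted p of 9.25e-07 (SE, n = 36). RRM2, a ribonucleotide reductase subunit, rose by 0.74 ± 0.11 (adjusted p = 8.38e-06), TOP2A by 0.70 ± 0.10 (adjusted p = 2.05e-06) and the survivin gene BIRC5 by 0.69 ± 0.11 (adjusted p = 1.92e-05). The replication genes MCM3 (0.53 ± 0.08, adjusted p = 1.39e-05) and PCNA (0.47 ± 0.10, adjusted p = 0.000551) rose too. In all, 18 of 20 members rose, also when adjusted over the list alone, with a median slope of 0.54 and a camera adjusted p of 2.88e-15 (adjusted p = 0.00695 with an estimated correlation). With the log2 TMM factor in the fit 16 of the 18 still rose.

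Outside that list EXO1, a DNA repair exonuclease, rose by 0.85 ± 0.12 (adjusted p = 2.19e-06), the telomerase gene TERT by 0.89 ± 0.25 (adjusted p = 0.00913) and the early response gene FOS by 0.92 ± 0.23 (adjusted p = 0.00414). STAT3 fell by 0.56 ± 0.13 (adjusted p = 0.00222) and GZMB, which encodes granzyme B, by 1.36 ± 0.29 (adjusted p = 0.000976). DSC2, a desmosomal cadherin, fell by 1.30 ± 0.26 (adjusted p = 0.000389), with a slope of -0.65 when 1 line, HAIR_M, was left out. These 6 genes were also called with the log2 TMM factor in the fit, where the slope of GZMB was -0.79. BMP4, a secreted growth factor, fell by 1.65 ± 0.30 (adjusted p = 0.000151), a call that was lost without HAIR_M. ANXA1 had the largest positive slope (2.19 ± 0.78, adjusted p = 0.031), which turned to -0.23 without SUDHL16. CREB3L1, MET and DNAJB13 were among the genes that fell most, and FCER2, ITGAM, MDK and CXXC4 among those that rose most. With the log2 TMM factor the calls of CREB3L1 (adjusted p = 0.0669), MET (-0.65, adjusted p = 0.144), ANXA1, FCER2, ITGAM, MDK and CXXC4 were lost, and those of BMP4 and DNAJB13 were kept. The ITGAM call was lost without GRANTA519, the FCER2 call without GRANTA519 or VL51 and the MDK call without OCILY19 or RIVA, while the CXXC4 call was lost in 7 leave-one-out runs. SOX7 rose by 1.12 ± 0.44 (adjusted p = 0.0476) with a least-squares slope of -0.15, and was lost in 22 leave-one-out runs. ANXA1, FCER2, SOX7 and MDK passed by neither r nor rho with MKI67 (adjusted p from 0.22 to 0.62), and CXXC4 did not pass by r (adjusted p = 0.054). Least-squares slopes on MKI67 were also under 0.5 of those in the edgeR fit for ANXA1 (0.42), FCER2 (0.47), MDK (0.34) and BMP4 (-0.72).

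Across 2405 genes, 387 rose and 369 fell with MKI67 in the edgeR test, and 148 of the 756 stayed with the log2 TMM factor in the fit, where 132 rose and 29 fell. MYC target genes were higher (adjusted p = 0.0259; 5 of 13 rose, also 5 when adjusted over the list alone). Epithelial markers (adjusted p = 0.0449; 3 of 7 fell, 4 when adjusted over the list alone) and T and NK cell markers (adjusted p = 0.0449; 2 of 9 fell, also when adjusted over the list alone) were lower. Each of these 3 lists had an adjusted p = 0.836 with an estimated correlation, and none was called with the factor in the fit. Library size alone gave 109 rising and 23 falling genes, upper-quartile factors 86 and 60 with a median slope over all genes of -0.17 against 0.02, and the fit without SUDHL2 and GRANTA519 292 and 144. A filter at 50 CPM gave 374 rising and 225 falling.

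MYC, the growth-promoting transcription factor, was highest in OCILY19 (6999 CPM), JEKO1 (6091 CPM) and OCILY8 (5809 CPM) and lowest in UPN1 (168 CPM) and U2932 (187 CPM). With it 246 genes rose and 383 fell, but 1 of the 629 stayed with the log2 TMM factor in the fit. That gene was CACNG6, a calcium channel subunit, with a slope of -0.91 ± 0.15 (SE, n = 36, adjusted p = 0.000835), and -0.86 with the factor (adjusted p = 0.0085). In the fit without the factor the MYC targets HSPD1, a mitochondrial chaperone (0.25 ± 0.08, adjusted p = 0.0236), and CAD, of pyrimidine synthesis, rose, as did NME1, SRM and TERT. Of these, TERT passed by neither r nor rho with MYC (adjusted p = 0.089 and 0.29). In the edgeR fit, then, 5 of 13 MYC target genes rose, also when adjusted over the list alone (camera adjusted p = 0.00987; adjusted p = 0.585 with an estimated correlation). Cancer-testis genes were lower (adjusted p = 0.00935; 3 of 7 fell, 5 when adjusted over the list alone; adjusted p = 0.585 with an estimated correlation), among them MAGEC1 (-0.67 ± 0.17, adjusted p = 0.0126). T and NK cell markers were lower (adjusted p = 0.0468; 3 of 9 fell, also when adjusted over the list alone; adjusted p = 0.585 with an estimated correlation). Cell cycle genes were tested as higher with 0 of 21 called (adjusted p = 0.0468; 0 when adjusted over the list alone; adjusted p = 0.733 with an estimated correlation), with a median slope of 0.06 that turned to -0.09 under library size alone. The calls for T and NK cell markers and cell cycle genes were lost without MEC1. The CAD and HSPD1 calls were lost without OCILY8, that of TERT without OCILY19, that of NME1 in 5 leave-one-out runs and that of SRM in 6. Without MEC1 3 of the 13 MYC target genes rose. With the log2 TMM factor in the fit none of the 4 lists was called (adjusted p = 0.147 for MYC target genes). In that fit NF-kB target (adjusted p = 1.48e-05), activated B-cell (adjusted p = 0.00759), JAK-STAT target (adjusted p = 0.00759) and plasma cell genes (adjusted p = 0.0122) were tested as lower with no member called and a correlation of 0.01, and an estimated correlation was not tried in that fit. Library size alone gave 5 genes, upper-quartile factors 7, the fit without MEC1 437 and that without OCILY8 188. Library size alone shifted the median slope of all genes to -0.10, from 0.05.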

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

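Chosen only after results were seen were the alternatives with the log2 TMM factor, those without MEC1, leaving each line out of the slopes, and the scalings tried on the lines low in IRF4 or high in CCND1. The 7 lines under 10 CPM of IRF4 and the 4 lines above the CCND1 gap were found under all 4 scalings tried. Under all alternatives run, 152 to 316 genes had an SD above 2, 9 to 11 lists were coherent (8 without them) and 15 to 23 of the relations passed. Of 660 alternative correlations of the fixed relations 623 kept their side of the threshold, 23 fell below it, 14 came past it and 0 turned direction. The runs with 1 line left out entered these 660 only by the lowest and highest r of each relation. Over all such runs, 9 relations had a call that changed with 1 line left out. Of 1786 alternative values of the 151 slopes that the naming rule selects 1371 kept their side of the threshold, 402 fell below it and 13 turned direction. Alternatives for IRF4 and CCND1 slopes were not run, as neither slope was fitted.

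The fits over all genes depended on the scaling and the lines. With 50 CPM as background a median of 1354 genes per line lay above it against 2436, because that limit is higher. Against 106 genes, BCL6 had 572 with upper-quartile factors, 723 with library size alone, 354 with the DESeq2 Wald test, 48 with limma-voom, 184 by rank, 609 without its 2 farthest lines, 165 with the log2 TMM factor and 90 (without OCILY19) to 210 (without SUDHL16) with each line left out. Against 629, MYC had 7 with upper-quartile factors (456 at an unadjusted p under 0.05), 5 with library size alone, 1 with the log2 TMM factor (173 at an unadjusted p under 0.05) and 188 (without OCILY8) to 797 (without GRANTA519) with each line left out. The DESeq2 Wald test gave the most for MYC, 857. Against 756, MKI67 had 146 with upper-quartile factors, 132 with library size alone, 456 with log2 library size added, 436 without its 2 farthest lines and 161 with the log2 TMM factor. It had more with DESeq2 size factors (1059), the DESeq2 Wald test (1089), rank (923), limma-voom (892) and without MEC1 (920). With each line left out it had 567 (without SUDHL6) to 962 (without DB). Lists called fell from 7 to 1 with BCL6 under an estimated correlation, from 4 with MYC to 0 under an estimated correlation, 2 with library size alone and 2 without MEC1 (with the log2 TMM factor 4 were called, none of them the same), and from 4 with MKI67 to 1 under an estimated correlation, 1 with library size alone and 1 with the log2 TMM factor. In the fit on MYC with the log2 TMM factor 414 of the 629 genes kept their direction, and the slopes of GZMB (0.171), KRT18 (0.156), S100A8 (0.12), PDGFRA (0.091), IL6 (0.081), MAGEB2 (0.054), CTLA4 (0.043), KLRD1 (0.037), CCL1 (0.034) and KRT19 (0.031) turned upward and that of STAT2 (-0.071) downward. With limma-voom the slope of SOX7 turned on MYC (-0.057) and on MKI67 (-0.165). With 1 line left out, which those 1786 values do not cover, slopes also turned for DNTT (-0.22), SOX7 (-0.15) and CEBPD (-0.02) on MYC without OCILY19, and for ANXA1 (-0.23) and SOX7 (as low as -0.13) on MKI67. For these changes, apart from those with the log2 TMM factor, fewer lines or a higher limit, the cause was not tested. Counting error limits genes near the floor, and 1 library per line leaves the spread between cultures of a line unmeasured.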

Other observations

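Levels of single apoptosis and chemokine receptor genes differed between lines. BCL2, the inhibitor of mitochondrial apoptosis, ran from 21.1 CPM in SUDHL10 and 30.5 CPM in OCILY7 to 9215 CPM in OCILY8. BCL2A1, a related inhibitor, was highest in SUDHL2 (4949 CPM) and FARAGE (4423 CPM), and BIK, which promotes apoptosis, in SUDHL16 (916 CPM). CXCR4, the receptor for CXCL12, was highest in JEKO1 (7932 CPM) and lowest in DB (19.5 CPM), while CCR7 was highest in VL51 (7671 CPM) and lowest in DB (9.62 CPM). TERT was highest in OCILY19 (1405 CPM), and IL10, an immunosuppressive cytokine, in SUDHL16 (197 CPM) and SUDHL2 (87.9 CPM).

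Single lymphocyte markers also varied between lines. MS4A1, which encodes CD20, was at 24.0 CPM in SUDHL16 and 32.6 CPM in OCILY19 against 4675 CPM in SUDHL4. CD3D, a component of the T-cell receptor complex, was highest in REC1 (490 CPM) and KARPAS1718 (333 CPM), while the members of the T and NK cell marker list had a median of 18.7 CPM.

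All tests given below were chosen only after the result was seen, except the permutations of BCL6, MYC and MKI67 over the lines, and as the labels give no groups no biological explanation was tested.

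The number of genes with slopes on MYC, MKI67 and BCL6 was weighed against library composition. Chance arrangements of the lines are argued against for all 3. Among 100 permutations and the real arrangement, only the real one gave as many genes for BCL6 (106, highest other 30), MYC (629, highest other 36) and MKI67 (756, highest other 447). Still, 3 other arrangements of MKI67 gave over 100 genes, and 100 permutations cannot exclude chance. With the log2 TMM factor in the fit 97 of the 106 genes stayed for BCL6 and 16 of the 18 cell cycle members for MKI67, which argues against composition as the whole cause there. For MYC 1 of the 629 genes stayed and the median absolute slope went from 0.48 to 0.06, so composition remains a candidate explanation. The TMM factor divides both sides of each slope, so composition and its scaling cannot be told apart, and the permutations cover neither. Library size alone gave 5 genes for MYC. A library at fault in MEC1 alone is argued against by the 427 genes kept without it. For the other 738 genes of MKI67, 132 stayed and the median absolute slope went from 0.52 to 0.26, so a composition effect and an effect of MKI67 cannot be told apart, because both vary along the same lines.

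CCND1 was low in JEKO1, UPN1, SP53, SP49 and REC1, which are known as carriers of the translocation that activates it. Counting depth is argued against, since the highest upper 95% bound in the 5 lines was 96.4 CPM against a lower bound of 2020 CPM in JVM2. Labels exchanged with another line of the panel are argued against too, since the fifth highest CCND1 level of all lines was 270 CPM. It remains possible that the probe lies outside the transcripts of these lines, and this could not be decided. CCND2 and CCND3 together reached at most 196 CPM in the 5 lines against a panel median of 472 CPM, but RIVA, which is not one of them, was as low at 160 CPM, so a cyclin that the probe misses and a low level of all D-type cyclins cannot be told apart.

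SP49 with SP53, and SUDHL2 with TMD8, were the most alike of 630 pairs of lines, at a Spearman rho across genes of 0.952 and 0.939 against a median of 0.804, where genes are not independent replicates. A single library deposited under both names is argued against, since 78.6% and 81.9% of genes with at least 100 counts in both differed beyond the 99% range of counting error. After regression on the log2 TMM factor, with each gene centred on its mean, the pairs had correlations of 0.558 and 0.5. They still ranked 2 and 3 of 630, behind JVM2 with HC_1 (0.583), which argues against shared composition as the whole cause. On this centred scale the median was -0.0265, so these values cannot be set against 0.952 and 0.939. A shared origin of the lines may remain, as 74 and 123 genes were over 4-fold apart against a median of 528. That number cannot be set against the difference between cultures of 1 line, since no line was measured more than once, so shared origin and likeness of distinct lines cannot be told apart.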
